A study of Saccharomyces cerevisiae with 13 samples.

How the data were processed

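Budding yeast of the W303 strain in an SSD1-V background were held in G1 with the mating pheromone alpha factor, released into rich medium and sampled at 0 min and every 10 min up to 120 min. Each of the 13 samples was hybridised to a two-colour array, with its own cDNA in Cy5 and cDNA from an asynchronous W303a culture in Cy3, per the labels. The SSD1 allele of that culture is not given in the sources used here. No dye swap was made and each time point has 1 array, so there are no replicates and the spread used in every test below is that of the arrays around a fitted curve. The p-values therefore measure departures from a smooth curve in 1 culture, not the variation between cultures.

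The deposited values are log ratios per open reading frame, taken here as log2 of Cy5 over Cy3. The log base and the direction of the ratio are not given in the sources used here, nor are the scanner, the background correction, the normalization method or the signal over background of any spot. The direction is called likely from the dyes in the labels and from the pheromone-induced gene FIG1, which stood at 4.53 on the 0 min array. A ratio of the opposite sign would turn every difference and shift every peak time by 30 min, and natural logarithms would make every size larger on the log2 scale. The authors' values had been centred: array means lay within 0.003 of 0, and array medians were -0.02 at 0 min, -0.03 at 10 min, -0.005 at 20 min, -0.01 at 40, 70 and 80 min, 0.01 at 50 min and 0 on the others. Arrays 30 min apart correlated at a mean r of -0.50 on gene-centred values; the labels state the dyes and opposite positions of the cycle can oppose each other, so the direction was kept. The values were used as deposited, without further normalization.

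The table held 6295 rows, of which 108 were empty on every array and 6168 were measured on every array. Names came from a RefSeq gene table of assembly R64: 5768 rows matched by locus tag and 49 by synonym, while 458 unmatched rows were kept under their open reading frame name. A further 20 rows carried no readable gene name and stayed out of every comparison; their periodicity was looked at separately. For 27 genes with more than 1 row the rows were averaged. The median correlation between the rows of such a gene was 0.58, so their values are less certain. This left 6140 genes, of which 6137 were measured on at least 10 arrays. No information on strand or probe sequence was used, so near-identical copies such as the histone gene pairs, overlapping genes and copies of transposons may share signal.

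Periodicity was tested with limma 3.58.1 in R 4.3.3. Each gene was fitted with an intercept, a linear time term and a cosine and sine of 60 min period. That period follows from the series' design text, which gives 2 cycles for the course of 120 min. The moderated F test of the cosine and sine terms was adjusted over all genes by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called periodic. The swing is the fitted peak-to-trough difference on the log2 scale, with its standard error from the fit, and the peak time is given in min after release, modulo 60. Cycle length was searched from 40 to 90 min in steps of 1 min over the members of 7 cell cycle lists, each gene scaled to unit variance, with a jackknife error over arrays. The cycles, 10 to 60 min and 70 to 120 min, were compared with limma's moderated F test of the interaction of cosine and sine with the cycle. The mean level against the reference was tested over the 12 arrays from 10 to 120 min with limma, at an adjusted p under 0.05 and an absolute mean above 1. The 0 min array was set against the mean of the 60 and 120 min arrays with no test, and list medians were placed among 10000 random lists matched on the deciles of the standard deviation over the later arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

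The gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They were 7 cell cycle lists (early G1 genes of cell separation and daughter cells, M/G1 targets of Mcm1, late G1 targets of SBF, late G1 targets of MBF with DNA replication genes, core histones, S/G2 targets of Hcm1 with spindle genes, and the G2/M CLB2 cluster) and 10 others (methionine and sulfate assimilation, phosphate regulon, pheromone response, ribosome biogenesis, ribosomal proteins, general stress, mRNAs associated with Ssd1, non-cycling controls, markers of other cell types, and auxotrophic marker genes of W303). The lists were written from general knowledge of yeast genes, not taken from these samples. Periodic shares were compared with Fisher's exact test, two-sided, adjusted over the 17 lists. The rule named the 3 members of largest amplitude among the periodic genes of each list and the 10 genes of smallest p outside the lists. For the 0 min comparison it named the 10 highest, the 10 lowest and the 3 largest absolute values per list described. For the comparison of cycles it named the 5 passing genes of smallest p with higher and the 5 with lower amplitude, and for the reference the 5 highest and 5 lowest passing genes. SSD1, BAR1, STE2, MFA1, CLN2, CLB2, HTA1 and SIC1 were always included.

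Alternatives covered centring and scaling of arrays, the minimum number of arrays, the choice between rows of a gene, the period, the linear term, a second harmonic, the variance model, thresholds and the omission of each array in turn. After the data were seen, a fit was added that allows a correlation between neighbouring arrays, estimated at 0.45 over all genes by restricted likelihood. It is called the fit with an estimated correlation, and was also used for the comparison of cycles and the mean level against the reference. The scripts were tested on simulated data with the real residual spread for 6121 genes, 200 of them changed. With independent noise the periodicity test recovered 38% of genes with a swing of 0.3, 80% at 0.6, 98% at 1 and 100% at 2, with 9 false calls. With correlated noise it made 47 false calls and recovered 58% at 0.3 and 92% at 0.6. With no gene periodic the periodicity test made 0 false calls with either noise. The comparison of cycles recovered 32% of genes with a first swing of 1 that shrank and 89% at 2, both with independent noise. The simulated shrinking was much stronger than that in the data, where the median periodic gene kept 65.6% of its first amplitude. Recovery of a change of that size was not simulated. The comparison of cycles made 7 false calls with independent noise and 183 with correlated noise, or 9 where the correlation was in the fit. With no gene changed it made 0 and 10 false calls with independent and correlated noise. The reference test by adjusted p alone, with 200 genes shifted, made 12 false calls with independent noise and 417 with correlated noise, or 11 where the correlation was in the fit. Signal over background is not known, so the number of arrays sets the only stated limit to precision.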

Results

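The study followed transcript levels through 2 cell cycles of budding yeast released from alpha factor, the pheromone that holds MATa cells in G1. The strain was W303 with the SSD1-V allele, which encodes a functional form of the RNA-binding protein Ssd1. The 13 samples form 13 groups of 1 array, from 0 min to 120 min at steps of 10 min, and each is a log2 ratio to the same kind of reference, an asynchronous W303a culture. Between 6178 and 6186 rows were measured per array. The standard deviation over rows was 0.39 at 0 min and 0.24 at 100 min. No time point was replicated, so each error given is the standard error of a fitted curve unless stated otherwise.

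Transcripts of the DNA replication machinery, the histones and the mitotic cyclins rose and fell in sequence after release. Across the genome, 1847 of 6137 genes tested were periodic at 60 min, or 30.1%, with a median swing of 0.40 and quartiles of 0.31 and 0.60. A swing of at least 1 was fitted for 198 of them. Peaks fell in all parts of the cycle, most often between 30 and 40 min (399 genes) and least often between 50 and 60 min (240 genes). The count depended on the noise model: 849 genes passed with an estimated correlation between neighbouring arrays, all of them among the 1847. It also fell to 1187 without the 40 min array.

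The cycle length was 63 min with a jackknife standard error of 1.69 min, from 130 genes of the cell cycle lists, against the 60 min implied by the sampling. Leaving out single arrays gave 63 or 64 min. The early G1 list alone gave 71 min, and the other lists lay between 60 min for the MBF list and 65 min for the CLB2 cluster. At other periods the number of periodic genes was 950 at 55 min, 1913 at 65 min, 1436 at 70 min and 0 at 50 min, where 1004 genes had an unadjusted limma p under 0.05.

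**Figure D1:**
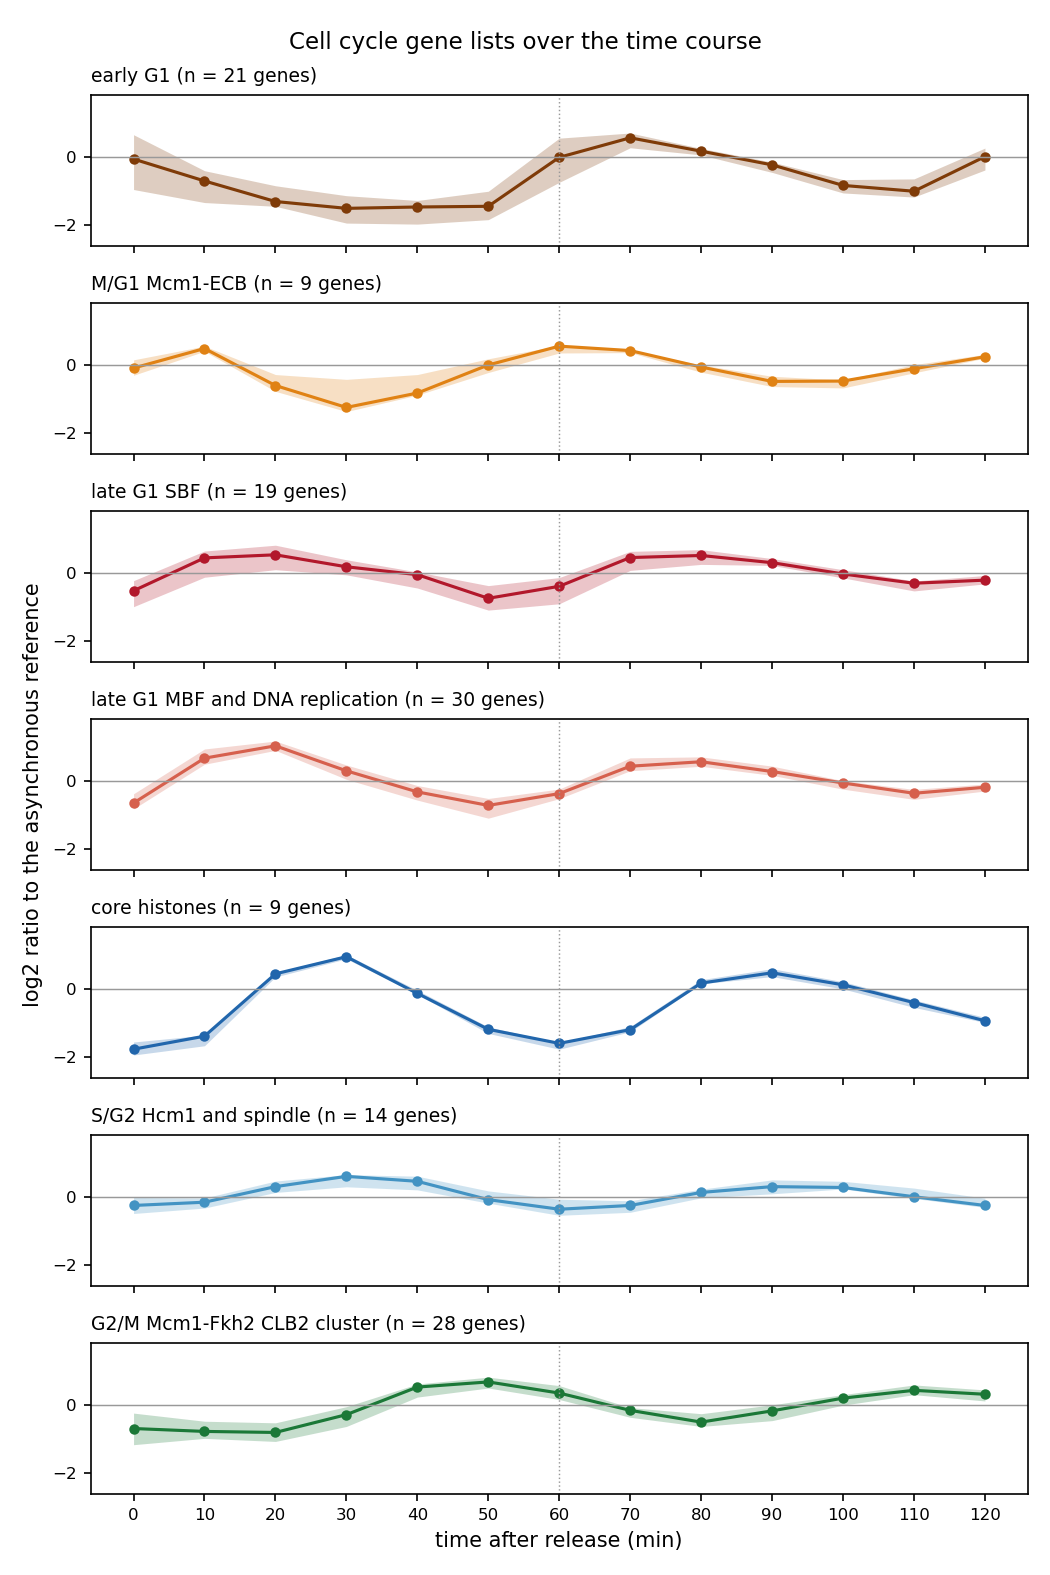
Median log2 ratio to the asynchronous reference (lines and points) and interquartile range (shading) over the measured members of 7 cell cycle lists, against time after release in min; the dotted line marks 60 min. The histone median was -1.77 at 0 min, and the early G1 list reached its fitted peak in the rise after 60 min.

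In the M/G1 list, of genes switched on at the end of mitosis, 8 of 9 measured members were periodic, as were 8 adjusted over the list alone (adjusted p = 0.0012, Fisher's exact test), with a mean peak at 4.1 min and a circular SD of 3.2 min. MCM5 (YLR274W) and MCM7 (YBR202W), subunits of the replicative helicase, had swings of 1.61 ± 0.18 and 1.52 ± 0.26. FAR1 (YJL157C), an inhibitor of G1 cyclin kinase needed for pheromone arrest, had a swing of 1.89 ± 0.43, but an adjusted p = 0.057 with an estimated correlation. In the early G1 list of daughter-cell and cell-separation genes, 14 of 21 were periodic, 15 adjusted over the list alone (adjusted p = 0.0014, Fisher's exact test), with a mean peak at 9.4 min, modulo 60, and a circular SD of 2.6 min. The median of all its members was -0.71 at 10 min, -1.51 at 30 min and 0.55 at 70 min, its highest value. Of the list, 7 members were periodic with an estimated correlation (adjusted p = 0.041, Fisher's exact test). HSP150 (YJL159W), a cell wall protein, had a swing of 2.22 ± 0.31, and SIC1 (YLR079W), the inhibitor of S phase cyclin kinase, 1.41 ± 0.26. EGT2 (YNL327W) and DSE4 (YNR067C), both active in cell separation, had swings of 2.39 ± 0.55 and 2.35 ± 0.54, with adjusted p = 0.058 and adjusted p = 0.060 with an estimated correlation. The early G1 call depended on single choices: 6 members were periodic without the 70 min array (adjusted p = 0.52, Fisher's exact test) and 5 without the linear time term (adjusted p = 1, Fisher's exact test).

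Late G1 transcripts followed. Of the MBF and DNA replication list, 29 of 30 members were periodic and 30 adjusted over the list alone (adjusted p = 2.3e-13, Fisher's exact test), with a mean peak at 20.2 min and a circular SD of 2.9 min. RNR1 (YER070W), the large subunit of ribonucleotide reductase, had a swing of 2.77 ± 0.33, or 6.81-fold. It stood at -1.37 at 0 min, 1.64 at 20 min, -1.66 at 50 min and 0.83 at 80 min. MCD1 (YDL003W), a cohesin subunit, had a swing of 2.71 ± 0.37, and POL30 (YBR088C), the sliding clamp of DNA polymerase, 2.31 ± 0.22. Of the SBF list, 14 of 19 members were periodic and 17 adjusted over the list alone (adjusted p = 3.7e-04, Fisher's exact test), with a mean peak at 22.1 min and a circular SD of 4.2 min. The G1 cyclin CLN2 (YPL256C) had a swing of 2.18 ± 0.30 and a peak at 19.5 ± 1.2 min. SVS1 (YPL163C) and the cell wall transglycosylase CRH1 (YGR189C) had swings of 2.38 ± 0.21 and 2.17 ± 0.24. The mean peaks of the SBF and MBF lists differed by less than the spread over the members of either list.

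All 9 histone genes were periodic, both over all genes and adjusted over the list alone (adjusted p = 1.1e-04, Fisher's exact test). Their peaks were the most tightly grouped of the cell cycle lists, at 30.0 min with a circular SD of 0.55 min, and the median swing was 2.24. HTA1 (YDR225W) and HTA2 (YBL003C), both histone H2A genes, had swings of 2.42 ± 0.23 and 2.45 ± 0.24, and HHF1 (YBR009C), for histone H4, 2.40 ± 0.22. These genes have near-identical copies that the arrays may not tell apart. Of the S/G2 list, 12 of 14 members were periodic and 12 adjusted over the list alone (adjusted p = 1.1e-04, Fisher's exact test), with a mean peak at 33.9 min and a circular SD of 6.0 min. Its largest swings were 1.32 ± 0.15 for the transcription factor FKH1 (YIL131C), 1.28 ± 0.15 for the microtubule protein STU2 (YLR045C) and 1.23 ± 0.14 for the spindle motor CIN8 (YEL061C). In the CLB2 cluster, 27 of 28 members were periodic and 28 adjusted over the list alone (adjusted p = 1.2e-12, Fisher's exact test), with a mean peak at 47.7 min and a circular SD of 3.8 min. CHS2 (YBR038W), the chitin synthase of the septum, had a swing of 1.84 ± 0.39, the polo kinase CDC5 (YMR001C) 1.52 ± 0.27 and the mitotic cyclin CLB2 (YPR119W) 1.49 ± 0.31. At most 1 of 10000 random lists of periodic genes was as tightly grouped in time as any of these 7 lists. Tight grouping was not particular to them. The share of random lists as tight was 1e-04 for the 6 periodic ribosome biogenesis genes, 0.0024 for 4 of pheromone and 0.0027 for 3 controls. It ran from 0.12 to 0.83 for the methionine, stress, phosphate and Ssd1 lists. With an estimated correlation 6 M/G1, 13 SBF, 26 MBF, 9 histone, 12 S/G2 and 23 CLB2 cluster genes were periodic, and each of these lists passed.

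**Figure D2:**
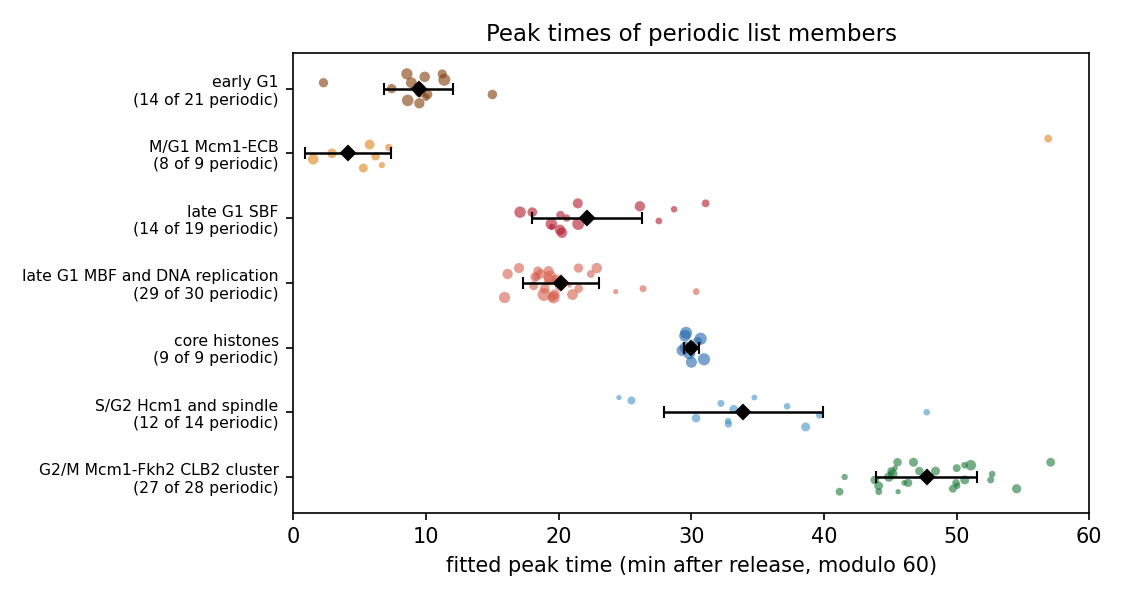
Fitted peak time in min after release, modulo 60, of each periodic member (circles, area in proportion to the swing) of 7 cell cycle lists, with the circular mean and circular SD over members (diamonds and bars). The lists' means run from 4.1 min for the M/G1 list to 47.7 min for the CLB2 cluster.

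None of the 10 other lists passed as enriched in periodic genes (adjusted p from 0.11 to 1, Fisher's exact test). The ribosomal protein list held 1 periodic gene of 15, RPL25 (swing 0.23 ± 0.07), and 0 adjusted over the list alone (adjusted p = 0.11, Fisher's exact test); RPL25 had an adjusted p = 0.22 with an estimated correlation. Without the 0, 10, 30, 90, 100, 110 or 120 min array the list had 0 periodic members, a lower share than that of other genes (adjusted p from 0.0086 to 0.037, Fisher's exact test), but with an estimated correlation its 0 members did not pass as depleted (adjusted p = 0.47). Of the ribosome biogenesis list, 6 of 18 were periodic and 7 adjusted over the list alone, with a mean peak at 39.3 min; NSR1 (swing 0.41 ± 0.09) and NUG1 (0.37 ± 0.07) led it, beside UTP10 with an adjusted p = 0.055 with an estimated correlation, and 1 member was periodic without the 40 min array. With that correlation 2 members of the ribosome biogenesis list were periodic, 3 of the stress list, 1 of the phosphate list and 0 of the methionine list. The methionine list held 2 of 12, MET3 and MET10, and 0 adjusted over the list alone, with adjusted p = 0.19 and adjusted p = 0.16 for these genes with an estimated correlation; without the 60 min array it held 0 (adjusted p = 0.046, Fisher's exact test). The phosphate list held 2 of 13 and 1 adjusted over the list alone: the acid phosphatase PHO5, with an adjusted p = 0.055 with an estimated correlation, and the alkaline phosphatase PHO8, with a swing of 0.52 ± 0.07 and a peak at 21.3 min. Without the 0 min array the phosphate list had 9 periodic members (adjusted p = 0.0093, Fisher's exact test). The general stress list held 5 of 19, also 5 adjusted over the list alone, with peaks on opposite sides of the cycle: SSA4, an Hsp70 chaperone, at 41.0 min and TPS2, an enzyme of trehalose synthesis, at 1.7 min. The hexokinase HXK1 had an adjusted p = 0.056 with an estimated correlation, and 2 members were periodic without the 40 min array.

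Of the mRNAs associated with Ssd1, 8 of 16 were periodic and 8 adjusted over the list alone, a share not shown to differ from that of other genes (adjusted p = 0.19, Fisher's exact test). TOS6 (YNL300W), a cell wall protein gene, had the largest swing of all periodic genes, 2.78 ± 0.35, with a peak at 23.6 min. The peaks of the 8 were spread over the cycle, with a mean resultant length of 0.16 on a scale where 1 is full agreement. The call depended on single arrays: 13 members were periodic without the 0 min array (adjusted p = 1.1e-04, Fisher's exact test), 8 without the 40 min array (adjusted p = 0.012) and 8 without the 70 min array (adjusted p = 0.028). With an estimated correlation 6 were periodic (adjusted p = 0.039, Fisher's exact test). CLN2, HSP150, SRL1, CTS1 and DSE2 also stand in the G1 lists. SSD1 itself (YDR293C) had a swing of 0.28 ± 0.12 and did not pass (adjusted p = 0.18).

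In the pheromone list 4 of 26 members were periodic and 3 adjusted over the list alone (adjusted p = 0.21, Fisher's exact test), against 9 without the 0 min array. The receptor gene STE2 had a swing of 1.84 ± 0.34, and MFA2, which encodes a-factor, 1.69 ± 0.28. The pheromone protease BAR1 had a swing of 2.01 ± 0.57 and an adjusted p = 0.13 with an estimated correlation, and MFA1 did not pass (adjusted p = 0.14). Of 9 genes chosen as controls that do not cycle, 3 were periodic, also 3 adjusted over the list alone (adjusted p = 1, Fisher's exact test). TUB1, for alpha-tubulin, had a swing of 0.77 ± 0.13 and a peak at 39.6 min; TFC1 and UBC6 had adjusted p = 0.082 and adjusted p = 0.15 with an estimated correlation. Among 12 markers of alpha cells, diploids and meiosis, 1 was periodic and 0 adjusted over the list alone: STE3, with a swing of 0.23 ± 0.07 and an adjusted p = 0.17 with an estimated correlation. None of the 6 auxotrophic marker genes was periodic, and 0 were adjusted over the list alone.

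The 10 genes of smallest p outside the lists covered several phases. ASF1, a histone chaperone, peaked at 18.2 min with a swing of 1.65 ± 0.14, and HIF1, a partner of a histone acetyltransferase, at 22.4 min with 1.19 ± 0.12. The ceramide synthase gene LAC1 (0.87 ± 0.07), YJR157W (1.59 ± 0.13), YNL013C (0.67 ± 0.06) and MFB1 (0.79 ± 0.08) peaked between 30.0 and 33.8 min. SUR1, of sphingolipid synthesis, peaked at 16.5 min with 0.97 ± 0.09, and HOR7 at 11.6 min with 0.91 ± 0.09. The cell wall gene SED1 peaked at 6.6 min with 1.40 ± 0.12, and ATG42, for a vacuolar carboxypeptidase, at 58.7 min with 0.93 ± 0.08.

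The sampling over 2 cycles allows a comparison of the oscillation in the first and the second cycle. The fitted swing of most periodic replication, histone and mitotic genes was smaller in the second, in 28 of 29 MBF genes, 9 of 9 histone genes and 27 of 27 CLB2 cluster genes. No test was made per list, and gene by gene 0 genes passed with an estimated correlation (192 at an unadjusted limma p under 0.05). That correlation was estimated with 1 amplitude for both cycles, so the 0 does not decide whether the change is noise. Over the 1847 periodic genes the median log2 amplitude ratio, second over first, was -0.61, with quartiles of -0.98 and -0.21 and a jackknife standard error of 0.19 over arrays. This is 65.6% of the first amplitude. The ratio was below 0 for 1540 genes and above 0 for 307. In the MBF list the median swing was 1.87 in the first cycle and 1.06 in the second, and in the histone list 2.77 and 1.62. In the CLB2 cluster the medians were 1.61 and 0.96. The M/G1, SBF and S/G2 lists had median ratios of -0.86, -0.62 and -0.63. The early G1 list had a median ratio of 0.19 with quartiles of -0.12 and 0.27, and 9 of 14 periodic members were higher and 5 lower in the second cycle. Its median ratio was -0.26 without the 10 min array, -0.073 without 30 min, -0.20 without 50 min and 1.43 without 60 min, and 0.012 with an estimated correlation. Its median swings were 1.62 and 1.56, and its difference from the other lists was not tested. The median level of its periodic members was -1.02 in the first cycle and -0.22 in the second. EGT2 stayed between -3.05 and -2.69 from 10 to 50 min and reached 0.55 at 70 min. On the 60 min scale the median shift of the peak in the second cycle was 1.55 min over the periodic genes, with quartiles of -1.35 and 4.14 min on both sides of 0. By list it was 8.58 min for early G1, 3.71 for M/G1, 3.16 for histones, 2.24 for the CLB2 cluster, 2.04 for S/G2, 0.85 for MBF and 0.73 for SBF. Among the periodic genes of other lists it was 10.72 for 2 of methionine, 3.42 for 3 controls, 2.27 for 8 of Ssd1 and 1.90 for 4 of pheromone. It was -6.21 for the 5 stress genes, -2.67 for the 6 of ribosome biogenesis and -0.34 for 2 of phosphate. Lists with 1 periodic gene had -0.74 (ribosomal proteins) and -1.555 (markers of other cell types). No shift was tested.

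**Figure D3:**
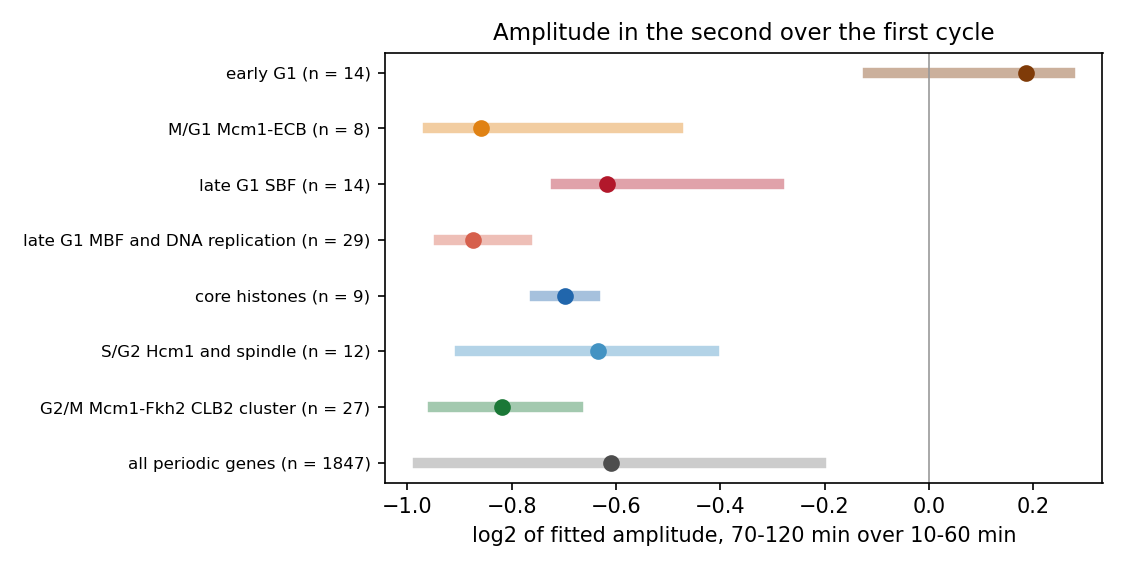
Median (points) and interquartile range (bars) of the log2 ratio of fitted amplitudes, 70 to 120 min over 10 to 60 min, for the periodic members of 7 cell cycle lists and for all 1847 periodic genes. Values below 0 mean a smaller swing in the second cycle; the early G1 list had a median of 0.19 and quartiles on both sides of 0.

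Gene by gene, limma's interaction test called 34 of 6135 genes different between the cycles, 30 with lower and 4 with higher amplitude in the second, and 932 had an unadjusted p under 0.05. The 4 higher were PRY3, SUN4, HO and FAA3, the 5 lower of smallest p OLE1, TIP1, PDS5, YML119W and YNK1. The test responds to a shift of the peak as well as to amplitude. Higher and lower therefore give only the direction of the fitted amplitude, not what the call rests on. HO (YDL227C), the endonuclease of mating type switching, had a swing of 0.40 in the first cycle and 2.03 in the second (adjusted p = 0.012). OLE1 (YGL055W), the fatty acid desaturase, had 1.64 and 0.40 (adjusted p = 0.0061), and the cohesin factor PDS5 (YMR076C) 2.36 and 1.22 (adjusted p = 0.0093). SSD1 did not pass (adjusted p = 0.41). By list, 6 MBF genes passed and 21 adjusted over the list alone, 2 and 20 in the CLB2 cluster, 2 and 6 in M/G1, 1 and 7 in SBF, 0 and 7 among histones and in S/G2, and 1 and 3 in early G1. Among the other lists the stress list had 0 and 7, the pheromone list 0 and 4, the Ssd1 list 1 and 3, the phosphate list 1 and 1, the methionine list 0 and 1, and the remaining lists 0 and 0. With an estimated correlation 0 genes passed, with 192 at an unadjusted limma p under 0.05. The count was 3 without the 80 min array, 8 without 110 min, 16 without 100 min, 18 without 50 or 90 min, 87 without 10 min and 235 without 60 min.

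In place of replicates, arrays at like positions of the cycle were compared. Across genes, on values centred per gene, arrays 60 min apart had a mean Pearson r of 0.37 ± 0.18 (SD over 6 pairs), from 0.08 for 30 and 90 min to 0.56 for 50 and 110 min. The mean Spearman value was 0.24. Arrays 30 min apart, at opposite positions of the cycle, had a mean r of -0.50 ± 0.15 (SD over 9 pairs). Genes are not independent replicates, so no p is attached.

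The 0 min array holds cells still under arrest, and it was set against the 60 and 120 min arrays, which lie 1 and 2 cycles later without pheromone. Mating genes stood far higher under arrest. Of 6129 genes, 68 were at least 1 higher and 54 at least 1 lower at 0 min. Between the 60 and 120 min arrays the corresponding numbers were 1 and 6. All 26 pheromone genes were higher at 0 min, 21 of them by at least 1, and 25 exceeded every later array. Their median difference was 2.24, and 0 of 10000 random lists were as high. The 10 highest genes of all were FIG1, AGA1, ASG7, PRM1, FIG2, FUS1, PRM2, PRM3, FUS2 and AGA2, all in that list. FIG1 (YBR040W), active in mating, was higher by 4.18, or 18.2-fold, and the agglutinin anchor AGA1 (YNR044W) by 3.84. The levels after release differed between genes: FUS1 stood at 3.40 at 0 min and 0.16 at 10 min, FIG1 at 4.53 and 2.76, and MFA1 at 1.85 and 1.66. STE2 and BAR1 were higher at 0 min by 1.24 and 1.82. With 1 array at 0 min these differences have no replicate check and no p.

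**Figure D4:**
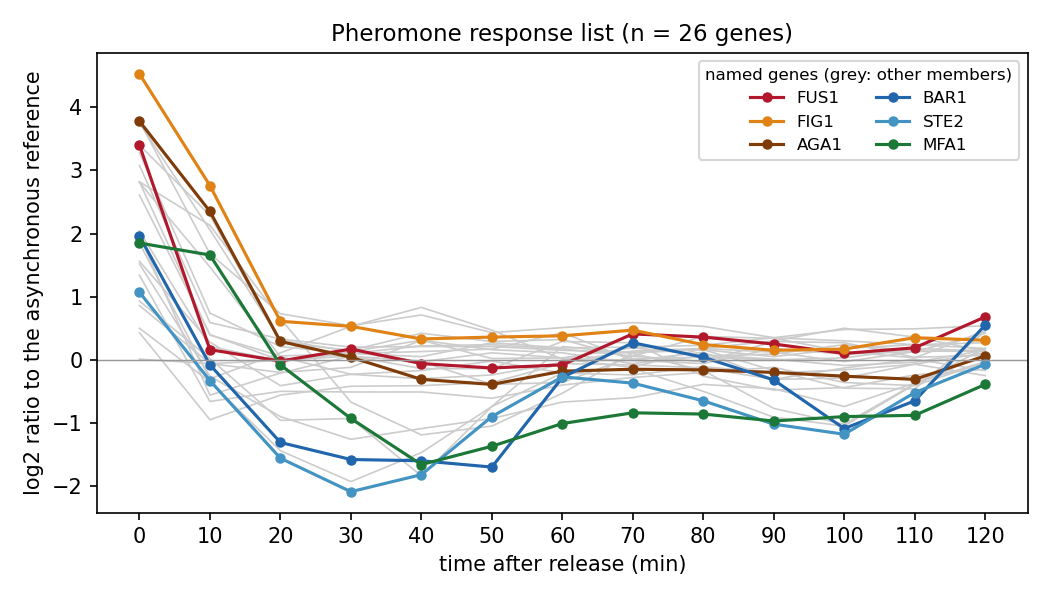
Log2 ratio to the asynchronous reference against time after release in min for the 26 genes of the pheromone list, 1 array per time point; 6 named genes are coloured and the others grey. FUS1 stood at 3.40 at 0 min and 0.16 at 10 min, where FIG1 stood at 2.76.

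The CLB2 cluster was lower at 0 min, with a median difference of -0.95, 13 of 28 members at least 1 lower and 0 of 10000 random lists as low; against the mean of all later arrays the median was -0.59. HOF1, a cytokinesis protein, differed by -2.18, CHS2 by -1.96 and CLB2 by -1.52. At 60 min CLB2 still stood at 0.40, so the later arrays are not all at the position of the arrest. The lowest genes of all were MRH1 (-2.67), AIM44 (-2.58), HOF1, SUR7 (-2.15), YRO2 (-2.12), YGP1 (-2.11), NCE102 (-2.04), CHS2, PST1 (-1.85) and YOR314W (-1.79). The phosphate list had a median of -0.39, with PHO12 at -1.50, PHO11 at -1.44 and PHO3 at -1.325, and 15 of 10000 random lists were as low. Of its 13 members 10 were lower and 3 higher, 1 of these by at least 1. All 15 ribosomal protein genes were lower at 0 min, by a median of -0.17 (7 of 10000 random lists as low). The non-cycling controls had a median of -0.14 on the same array, with 7 of 9 lower (408 of 10000 random lists as low). The median of the Ssd1 list was 0.19, with 9 of 16 members higher and 7 lower, and 48 of 10000 random lists were as high. The median gap between its 60 and 120 min values was 0.34, larger than that difference. DSE2, CTS1 and SCW10, cell wall enzymes or daughter-cell genes, were higher by 2.46, 2.37 and 2.16. SSD1 was 0.35 higher.

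Among the other cell cycle lists, medians at 0 min were -0.28 for the early G1 list, -0.46 for M/G1, -0.27 for SBF, -0.34 for MBF, -0.44 for histones and -0.06 for S/G2. Against the mean of all later arrays these were 0.37, -0.01, -0.49, -0.68, -1.38 and -0.40 in the same order, so the early G1 sign turned. KAR3, a motor of nuclear fusion as well as of the spindle, was 1.85 higher, and PCL2, a G1 cyclin, 1.46 higher. CLN1 was at -1.29, CDC6 at -1.78 and MCD1 at -1.38. The methionine, ribosome biogenesis and stress lists had medians of 0.04, 0.00 and 0.10, and the auxotrophic markers 0.08. Against the mean of all later arrays the methionine and ribosome biogenesis medians were -0.098 and -0.025. The markers of other cell types had a median of 0.12, with the alpha-agglutinin gene SAG1 at 0.91 and the sporulation gene SPS4 at -1.58.

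The common reference allows each gene's mean level over the course to be set against asynchronous cells. The genes passing above 1 were transposon transcripts, though most of the transposon rows looked at did not pass. Genes of cell separation were among the lowest. Over the 12 arrays from 10 to 120 min, 4 of 6135 genes passed above 1 and 10 below -1. Above were YIL082W-A, the Ty3 retrotransposon, at 2.71 ± 0.12, YIL080W at 1.23 ± 0.13, and the Ty1 genes YML040W at 1.06 ± 0.06 and YJR026W at 1.00 ± 0.06. Of the 13 Ty1 rows with values that were looked at, a chosen set, the others did not pass above 1. Nor did the Ty3 row YIL082W, with means of 0.46 in the first cycle and 0.31 in the second. The 5 lowest were PRM7 (YDL039C) at -2.54 ± 0.12, BSC1 (YDL037C) at -2.27 ± 0.11, EGT2 at -1.48 ± 0.32, DSE4 at -1.22 ± 0.27 and the chitinase CTS1 at -1.16 ± 0.18. Without the minimum size, 2128 genes passed above 0 and 2100 below, against 1313 and 1388 with an estimated correlation, all of them among the former. From 10 to 60 min alone 8 genes passed above and 28 below, and from 70 to 120 min 5 passed below. No dye swap was made and the SSD1 allele of the reference is not given in the sources used here. Dye bias, a difference in allele and other differences between the cultures therefore cannot be told apart. The mean was taken over log ratios, while an asynchronous culture mixes cycle positions before the log is taken. A gene with a large swing can therefore lie below 0 at an equal average amount. How far this lowers the values of cell separation genes, the early G1 list and the histones was not tested.

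By list, 17 of 21 early G1 genes passed below 0 (17 adjusted over the list alone; median -0.67), and 8 of 9 histone genes did (8; median -0.40). Of the methionine list 11 of 12 passed above 0 (11; median 0.45), and of the stress list 16 of 19 (16; median 0.24). Of the ribosome biogenesis list 16 of 18 passed below 0 (17; median -0.25), of the ribosomal proteins 9 of 15 (9; median -0.12) with 1 above, and of the Ssd1 list 10 of 16 (10; median -0.17). The pheromone list split evenly, with 9 above and 9 below. The MBF list had 12 of 30 above and 0 below (median 0.09; 10 and 0 adjusted over the list alone), the CLB2 cluster 4 above and 10 below (2 and 7 adjusted over the list alone), SBF 4 and 5, S/G2 7 and 2, M/G1 0 and 6, and phosphate 1 and 5. The non-cycling controls had 2 above and 3 below, the markers of other cell types 2 and 3 (2 and 2 adjusted over the list alone), and the auxotrophic markers 2 and 3 (3 and 3 adjusted over the list alone), with LEU2 at -0.46 ± 0.03, CAN1 at -0.33 ± 0.03 and URA3 at -0.31 ± 0.02. SSD1 stood at -0.13 ± 0.04 (adjusted p = 0.0080), but had an adjusted p = 0.13 with an estimated correlation. With that correlation 15 early G1, 5 histone, 13 ribosome biogenesis, 7 ribosomal protein and 7 Ssd1 list genes passed below 0, and 8 methionine, 15 stress and 7 MBF genes above. The pheromone list then had 6 above and 7 below, the CLB2 cluster 1 and 5, SBF 3 and 3, S/G2 3 and 1, M/G1 0 and 2, phosphate 0 and 4, the non-cycling controls and the markers of other cell types 1 and 1, and the auxotrophic markers 1 and 3.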

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

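Of the tests in this part, the fit with an estimated correlation was chosen after the result was seen, and the tests that weigh the smaller swing were set after that pattern was seen but before their own results. The oscillation differed between the first and the second cycle, by a test of the difference itself, for 34 genes. The named genes had log2 amplitude ratios, second over first cycle, of 0.52 for PRY3, 0.23 for SUN4, 2.34 for HO and 0.38 for FAA3. They were -2.06 for OLE1, -0.88 for TIP1, -0.96 for PDS5, -1.07 for YML119W and -1.49 for YNK1. FAA3 was at -0.055 without the 30 min array. The test responds to peak time as well as amplitude. The fitted peak of PRY3 was at 3.1 min in the first cycle and 19.2 min in the second. Likewise it was at 48.976 and 21.035 min for SUN4 and at 56.89 and 13.41 min for FAA3. For OLE1 it was at 2.97 and 18.03 min, and for HO at 9.18 and 18.64 min. Peaks lay closer for TIP1 (6.45 and 12.85 min), PDS5 (19.65 and 21.865), YML119W (52.48 and 55.545) and YNK1 (21.69 and 26.275). How far each call rests on peak time was not tested. Of 99 splits of the 12 arrays into 6 and 6 that could be fitted, the real one included, 1 gave as many genes. The highest other split gave 18, so chance assignment of independent arrays is unlikely to give 34 genes. Only 100 of the 462 possible splits were drawn, however, and with scaled arrays the real count was itself 18. Noise that runs on from array to array is not covered by such splits. With an estimated correlation 0 of 6121 genes passed, with 192 at an unadjusted limma p under 0.05. That correlation was estimated with 1 amplitude for both cycles, so it can take up part of a real change. The 0 therefore does not decide between noise and a real difference. In simulated correlated noise the test as planned made 183 false calls with 200 genes changed, but 10 with none changed. The count ran from 3 without the 80 min array to 235 without 60 min, with 8 without 110, 16 without 100, 18 without 50 or 90, and 87 without 10 min.

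The smaller swing of most periodic genes in the second cycle was weighed further. Compressed ratios on the later arrays would shrink constant offsets too, but over the 487 genes that are not periodic and have an absolute mean over 0.3 the median second over first cycle mean was 0.94 (bootstrap interval 0.92 to 0.97), against an amplitude of 65.6%. With a 65 min period the median log2 ratio was -0.61, which met what had been set beforehand against a longer cycle. Each cycle was fitted apart, however, so a change of period acts on both amplitudes much alike. That value therefore does not decide on a longer cycle. A biological candidate explanation is that cells of the culture drift out of step, which should blunt sharp features more than the main wave: in 5 of 7 lists the second harmonic of the list mean fell more than the first, short of the 6 set beforehand, so loss of synchrony stays open. So does a real change between the first cycle after arrest and the next, which 1 culture cannot tell apart from it.

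Rows that no comparison used were also looked at. Of 20 rows without a readable gene name, 7 passed the periodicity test, a share near the 30.1% of all genes tested, the largest swing being 1.62. The median correlation between these rows was 0.02.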

How the results depend on the processing

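The correlation between neighbouring arrays and the 63 min period were chosen after seeing the data, and the cause of each change below was not tested unless stated. The main results run under the alternatives were the counts of genes, the cycle length, the agreement between arrays, and, by list, the periodic members, mean peaks, amplitude ratios and median levels; the counts of list members against the reference were run only with an estimated correlation. Of these values 1328 stayed the same, 72 moved, 23 gained a call, 13 lost one and 30 reversed, all of the latter list medians of level or amplitude with no test. A count stayed the same if it lay within a set factor of the main count. A mean or median did so if it lay within its own spread or error, and a list's periodic share if its test call was unchanged. Of the named genes' values, 1970 stayed, 278 lost their call, 25 moved, 7 gained a call and 1 reversed, FAA3 at -0.055 without the 30 min array and between that and 0.94 without single arrays. The orders of the arrays bear on the count of periodic genes: of 100 orders of the 13 arrays, the real one included, 1 gave as many as 1847, and the highest other gave 192. That argues against independent noise as the source of the count, but does not bear on single genes. With an estimated correlation 849 passed, under the 50% of calls set beforehand, so correlated noise stays open for the rest. Of 51 named periodic genes 38 passed with it.

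The number of periodic genes was 0 at 50 min and 950 at 55 min (922 shared), 920 with a second harmonic (887 shared), 198 with a swing of at least 1, 797 at an adjusted p under 0.01, and 1187 to 1919 without single arrays. At 50 min each of the early G1, M/G1, SBF, MBF, histone, S/G2 and CLB2 lists had 0 periodic members. At 55 min the early G1 list had 5 and the CLB2 cluster 9 (adjusted p = 0.53 and 0.073, Fisher's exact test). The early G1 list had 5 without the linear time term, 6 with a second harmonic, 6 at an adjusted p under 0.01, and 6 to 21 without single arrays. The Ssd1 list passed with 10 members at 65 min, 12 at 70 min, 13 without the 0 and 10 min arrays, 5 with a swing of at least 1, 6 at an adjusted p under 0.01, 6 with an estimated correlation, and had 7 to 13 without single arrays. The pheromone list passed with 4 members with a swing of at least 1. The ribosomal protein list passed as depleted with 0 members at 65 min, without the linear time term and without the 0 and 10 min arrays, and had 0 to 1 without single arrays. The ribosome biogenesis list passed as depleted with 0 members without the linear time term. The phosphate list had 1 to 9 and the methionine list 0 to 3 without single arrays.

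Mean peak times moved by more than the spread of their list as follows. The early G1 list peaked at 14.1 min with a 55 min period, 6.0 at 65 min, 1.5 at 70 min and 12.4 without the 0 and 10 min arrays, and from 8.7 to 12.7 min without single arrays. The M/G1 list peaked at 9.2 min with a 55 min period. The histones peaked at 31.6, 28.4 and 26.6 min with periods of 55, 65 and 70 min, 29.1 with the best period, 30.7 without the linear time term, and 29.4 to 30.7 without single arrays. The SBF and MBF lists peaked at 16.6 and 16.4 min with a 70 min period. The period shifts follow from the time scale itself.

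The genes differing between the cycles numbered 18 with scaled arrays, 21 at 55 min, 92 at 63 min, 166 at 65 min, 0 with an estimated correlation, and 3 to 235 without single arrays. With scaled arrays the median amplitude ratio was -0.71 for the MBF list, -0.40 for S/G2 and -0.62 for the CLB2 cluster. For the early G1 list it ran from -0.26 without the 10 min array to 1.43 without 60 min, and was below 0 without the 10, 30 or 50 min array. Over periodic genes only, r was 0.64 for arrays 60 min apart and -0.71 for arrays 30 min apart. Against the mean of all later arrays the 0 min median was 2.53 for the pheromone list, -0.59 for the CLB2 cluster, -0.013 for M/G1, -0.68 for MBF, -1.38 for histones, -0.40 for S/G2, -0.083 for the non-cycling controls and 0.0083 for the markers of other cell types. The sign turned for early G1 (0.37), methionine (-0.098) and ribosome biogenesis (-0.025). Against 60 min alone the pheromone list gave 2.44 and the controls -0.05, and the sign turned for S/G2 (0.005) and ribosome biogenesis (-0.12). Against 120 min alone the methionine median was -0.065 and the stress median 0. Against the reference 8 genes passed above and 28 below from 10 to 60 min, 5 below from 70 to 120 min, and 2128 above and 2100 below with no minimum size, or 1313 and 1388 with an estimated correlation as well. With that correlation and the minimum size 4 passed above and 10 below, as many as without it. List medians against the reference from 10 to 60 min and from 70 to 120 min were -1.09 and -0.27 for early G1, 0.53 and 0.37 for methionine, -0.17 and -0.32 for ribosome biogenesis, -0.18 and -0.065 for ribosomal proteins, 0.18 and 0.34 for stress, -0.26 and -0.093 for Ssd1, -0.11 and -0.18 for the auxotrophic markers and 0.085 and -0.14 for phosphate. From 70 to 120 min the sign also turned for SBF (0.03), pheromone (-0.005), the controls (-0.027) and the markers of other cell types (0.00083). Phosphate also turned with scaled arrays (-0.0071) and over all 13 arrays (-0.027), where pheromone was at 0.18. Without single arrays the sign turned for SBF (-0.046 to 0.015, above 0 without 60 min), the CLB2 cluster (-0.13 to 0.0014, above 0 without 20 min), pheromone (-0.032 to 0.064, below 0 without 10 min), the controls (-0.0073 to 0.018, below 0 without 30 min) and phosphate (-0.055 to 0.014, reversed in 9 of 12 runs).

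No paired analysis was possible because the time points, each with 1 array, share only 1 replicate number. Arrays 60 min apart pair positions of the cycle, not replicates, and a test of the difference within these 6 pairs was not made. The minimum of 7 arrays was not run for the agreement between arrays or the 0 min comparison, which use complete values. Signal over background is not known, so what weak spots limit was not analysed here.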

Other observations

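The tests of gene-name families, with and without an estimated correlation, and of the distance between neighbours were chosen after the data were seen, as were the Ty3 tests of shrinking ratios and of pheromone-made RNA, the comparison of orientations, and the choice of YIL080W and of the Ty1 rows. Genes sharing the first 3 letters of their symbol were compared with all other genes over 89 families of at least 8 measured members, left after families made of open reading frame names had been dropped on seeing a first pass. All 8 SDH genes, which encode succinate dehydrogenase, its assembly factors and related subunits, were periodic (adjusted p = 0.0020, Fisher's exact test), with a mean peak at 3.7 min and a circular SD of 2.8 min. There were 5 with an estimated correlation (adjusted p = 0.035, Fisher's exact test). Swings ran from 0.31 ± 0.08 for SDH3 to 0.72 ± 0.12 for SDH2. None of these genes was in a list fixed beforehand. Of 8 MNN genes, of protein mannosylation in the Golgi, 7 were periodic (adjusted p = 0.023, Fisher's exact test) with a mean peak at 33.0 min, among them MNN2 (0.52 ± 0.08) and MNN10 (0.47 ± 0.08), but with an estimated correlation the family's 4 did not pass (adjusted p = 0.18, Fisher's exact test). Of 9 POL genes 8 were periodic (adjusted p = 0.0098, Fisher's exact test), and 5 of these 9 are also in the MBF list; with an estimated correlation 6 were (adjusted p = 0.012, Fisher's exact test). POL4, of DNA repair, peaked at 45.1 min, away from the family's mean of 20.1 min. The SPC family passed only with an estimated correlation, where 7 of 14 genes were periodic (adjusted p = 0.030, Fisher's exact test). Without it 8 of 14 were (adjusted p = 0.26, Fisher's exact test).

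Ribosomal protein genes were periodic less often than other genes: 0 of 56 RPS genes (adjusted p = 2.5e-07, Fisher's exact test) and 3 of 76 RPL genes (adjusted p = 7.3e-07, Fisher's exact test), namely RPL25, RPL27B and RPL31A. With an estimated correlation 0 genes of either family were periodic, and both passed as depleted (adjusted p = 0.012 for RPS and adjusted p = 0.0014 for RPL, Fisher's exact test). The list of 15 ribosomal protein genes did not (adjusted p = 0.47, Fisher's exact test). Many of these genes have near-identical copies, so their rows are not independent. The ATP family had 10 of 18 members periodic near 7.7 min, which did not pass (adjusted p = 0.26, Fisher's exact test).

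Periodic genes that are neighbours on the chromosome peaked at similar times. For divergent pairs, which share an upstream region, the mean difference in peak time was 6.65 min over 183 pairs, against 14.9 min on shuffling the peak times (permutation p = 1e-04, the smallest that 10000 shufflings can give). This met what had been set beforehand for a shared upstream region, but that cause was then left open and cannot be told apart, because convergent pairs lay at 7.28 min over 164 pairs (permutation p = 1e-04), not beyond the spread of the divergent ones (permutation p = 0.41), and tandem pairs at 9.18 min. The convergent value met what had been set beforehand for overlapping transcripts read by the same spots. Overlap would not reach genes farther apart, and pairs 2 genes apart differed by 11.3 min and pairs 5 apart by 13.7 min. Pairs at these distances were not set against shuffled peak times, so they do not decide on overlap. Near-identical copies that lie side by side may share signal, and such pairs were not set apart. YRF1-4 and YRF1-5, for example, differed by 0.57 min in peak time. How far such pairs lower the means was not tested. The order of spots on the array, another possible explanation, was not analysed here.

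The Ty3 transcript YIL082W-A stood at 3.87 at 0 min and at 2.09 at 120 min. What had been set beforehand for a fault of this row alone was met, since YIL082W changed by only -0.16 between the cycles; the fault was left open, not accepted, because YIL082W was the only row with values of the 3 named beforehand, and YIL080W, from the same element, changed by -0.77. The second over first cycle mean was 0.74 for YIL082W-A and 0.52 for YIL080W. Its median was 0.94 (bootstrap interval 0.92 to 0.97) over the 487 genes that are not periodic and have an absolute mean over 0.3. That argues against an even shrinking of all ratios on the later arrays. Most of these genes lay far nearer the reference level than YIL082W-A, so a shrinking of large ratios alone stays open. A first test on 34 genes with a first cycle mean beyond 1, with a median of 0.39, was dropped because it was void, since 21 of them were periodic or in a list. Among the rest of the 34 the ratio ran from 0.27 for MRH1 to 1.34 for PRM7, a range that holds both Ty3 values. RNA made under pheromone that persists may also play a part, but was not shown to. The median change of the Ty3 rows was -0.62 beyond that of the 13 Ty1 rows, which was -0.15, close to the change of YIL082W. Only 1 of 3 Ty3 rows was highest at 0 min, against 9 of 13 Ty1 rows.

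In the 20 rows without a readable name the number of the locus was replaced by the word null. Of all locus numbers tried in its place, the best gave 19 locus tags of the reference on the same chromosome arm and strand, 0 of them in the table, and the next best gave 1 missing from the table. PRM7 and BSC1, which lie close together on 1 chromosome arm, stood at -1.01 and -0.97 at 0 min and at -3.19 and -2.91 at 120 min.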
